A study of Mus musculus with 8 samples.

How the data were processed

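The series measured messenger RNA levels in MCE301 cells, a mouse colonic epithelial cell line established from mice with a transgene for the SV40 large T-antigen in a form that depends on temperature. Cells were given 2 mM sodium butyrate, a short-chain fatty acid that inhibits histone deacetylases, for 0, 6, 12 or 24 h. Each of the 4 times has 2 arrays, 8 in all, and the group and replicate number of each array come from its title. The labels do not say that the 2 arrays of a time came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. No untreated cells at 6, 12 or 24 h are among the arrays, so time in culture and butyrate change together in every comparison.

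Per the labels and the series design, total RNA was labelled with phycoerythrin and hybridised to the Affymetrix Mouse Expression Array 430A, prepared as the manufacturer instructs. The deposited table holds 22690 probe sets with a linear intensity (signal) for each array and no missing value. The software that summarised probes into signals is not given in the sources used here. Every array had a 2% trimmed mean signal of 500.2, so the deposited intensities had been scaled to a common level, and they were used as deposited. The table has no detection calls. Median signals were 140.1 to 152.8, and 21.2% to 26.4% of the signals of an array lay below the pseudocount of 32, where a signal carries little information. For arrays, their number limits the precision: 2 per time.

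Of the 22690 probe sets, 64 were control probe sets, 20380 had 1 gene in the platform annotation, 691 had several genes and 1555 were not listed in it. Probe sets with several genes or none listed were named for no gene. Of the 20380, 20351 had an Entrez identifier found in the RefSeq gene table of assembly GRCm38.p6, which was used for names only and changed 0 symbols; the other 29 kept the annotation's symbol. No coordinates are given, since the files name no genome build.

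The choices in this and the next paragraph were made before the data were examined: the groups, the tests, the gene lists, the rule for the genes named and the alternatives not marked otherwise. Control probe sets were left out. A probe set was kept when at least 2 of the 8 arrays were above the median of all values, a signal of 144.7, which left 11505 probe sets, and each gene was represented by its kept probe set with the highest mean, which left 7340 genes. Signals were taken as log2(signal + 32), so fold changes are on that scale and understate the change of low signals. All 8 arrays were fitted in limma (version 3.58.1, R 4.3.3) with lmFit and eBayes, with a residual df of 4 and a prior df of 6.37. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, computed over the 7340 genes for each comparison. Errors given as ± are the SD of the 2 arrays of a time for signals and the standard error of the fit for log2 changes.

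The named genes are, for each comparison with 0 h, the 10 largest rises and 10 largest falls among called genes whose 2 groups of arrays did not overlap, with 4 and 4 for 12 h against 6 h and for 24 h against 12 h. Added to them are the 4 called members with the largest change in the direction of each called gene list, and 9 fixed genes: Cdkn1a, Ccnd1, Myc, H1f0, Gsn, Slc16a1, Alpl, Krt20 and Hdac1. Predicted and clone-only names were passed over. Alpl did not pass the filter and no probe set named H1f0 alone was found, so neither was tested. Genes named outside this rule, as examples of a list, were chosen after their values were seen. Of 32 gene lists fixed in advance, 28 had at least 5 tested members and were tested against 0 h with camera in limma, at a preset correlation of 0.01 and with the p adjusted over the 28 lists and 3 times; a test with an estimated correlation stands beside it. The lists with under 5 tested members were not tested: goblet, enteroendocrine and Paneth cell markers with 1 tested member, immune cell markers with 3, endothelial markers with 1, and butyrate transport and receptors with 4.

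The other kept probe sets of a called gene moved in the same direction in 97.4% of cases at 6 h, 96.3% at 12 h and 95.8% at 24 h. A second probe set was called in the opposite direction for 0 genes at 6 h, 3 genes at 12 h (Mtm1, Nectin2 and Snd1) and 7 genes at 24 h. Within a time, the 2 arrays correlated at r = 0.979 to 0.982 over all probe sets (the correlation is across probe sets, which are not independent), and at most 0.20% of their signals were identical, so the arrays of a time are not copies of each other. The Gapdh 3' to 5' signal ratio was 0.767 to 0.878 and that of Actb was 1.01 to 1.12.

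Replicate numbers are shared by all 4 times. The difference between array 1 and array 2 correlated between times at r = 0.125 to 0.382 over genes in all 6 pairs of times, which are values over 0.1, so the numbers were taken to pair the arrays, and the pairing comes from the data and not from a statement in the labels. The spiked hybridisation controls point the same way: bioC was 356.5 to 454.4 on the arrays numbered 1 and 554.8 to 733.2 on those numbered 2. The fit with the replicate number as a block has a residual df of 3, found 1 gene of 7340 with an effect of the number, and is given beside a result where it changes the call or moves a count by over 1.5 times.

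The fit was tested on simulated arrays for 24 h against 0 h with the means and spreads of the 7340 genes. Among 50 genes changed at each size, 32% were recovered at 1.5-fold, 90% at 2-fold, and 100% at both 4-fold and 8-fold, with 11 false calls. In the same simulation 0 of 100 unchanged lists were called, while a list of 30 genes shifted by 0.5 on the log2 scale had a camera adjusted p of 1.17e-16 with the preset correlation and 0.0559 with an estimated one. The simulated genes were drawn independently, so a call lost with an estimated correlation need not reflect correlated genes. Alternatives were a pseudocount of 8 and a higher one, quantile normalization, median centring, no filter, a stricter filter (at least 2 arrays above the 70th percentile, a signal of 436.4), all named probe sets, eBayes with a trend and robust settings, only the 4 arrays compared, a fold threshold of 2, the replicate block and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.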

Results

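The study asked which genes respond to sodium butyrate in colonic epithelial cells. MCE301 mouse colonic epithelial cells were exposed to 2 mM butyrate for 0, 6, 12 or 24 h, with 2 arrays at each time. Signals of 7340 genes were compared between each later time and 0 h, and between neighbouring times. The 2% trimmed mean was 500.2 on every array. Values are mean signals ± SD of 2 arrays, and adjusted p-values are from limma. Folds and ranks are for a pseudocount of 32 added to each signal, so those of genes with a mean near or below it depend on that choice.

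After 6 h with butyrate, Fos and Egr1 had the largest increases. Fos (probe set 1423100_at), a subunit of the AP-1 transcription factor, rose from a signal of 55.7 ± 16.8 to 1084 ± 209, a log2 change of 3.67 ± 0.22 (adjusted p = 2.98e-05). Egr1 (1417065_at), an immediate early zinc finger transcription factor, rose from 583.4 ± 87.9 to 6197 ± 275, a log2 change of 3.35 ± 0.16. Txnip, a protein that binds thioredoxin, rose 5.47-fold, and Ccn1, a secreted matricellular protein, rose 4.93-fold. The largest fall was that of Fst (1421365_at), the activin-binding protein follistatin, from 2700 ± 256 to 427.9 ± 4.38, a log2 change of -2.57 ± 0.20 (adjusted p = 0.000103).

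The other leading rises at 6 h were Dusp2, a phosphatase of MAP kinases, Sgtb, Fam117a, Usp2, Rab3a and Efna3, with log2 changes of 2.04 to 2.19 (over the alternatives, 1.15 to 2.72 for Usp2 and 1.22 to 2.56 for Rab3a, with low 0 h signals). The falls after Fst were Tlr3, a receptor for double-stranded RNA, Nupr1, Sco2, which serves cytochrome c oxidase assembly, the transcription factor Foxa1, Tacc2, the chromatin protein Hmga2, the lipopolysaccharide co-receptor Cd14, Ifit3 and Cutal. Their log2 changes ran from -2.24 for Tlr3 to -1.75 for Cutal. Of the genes fixed in advance, the G1 cyclin Ccnd1 fell from 11290 ± 864 to 5772 ± 277, a log2 change of -0.96 ± 0.16 (adjusted p = 0.00324), and Myc fell from 1106 ± 40.7 to 498.2 ± 143 (adjusted p = 0.00438). Krt20, a keratin of differentiated intestinal epithelium, rose from 1377 ± 364 to 3471 ± 675 (adjusted p = 0.00551), a call lost without the 0 h replicate 1 array (adjusted p = 0.0511). Cdkn1a, which encodes the CDK inhibitor p21, was at 3797 ± 113 at 0 h and 2644 ± 60.5 at 6 h. The difference did not pass the test (log2 change -0.52 ± 0.18, adjusted p = 0.0767), although it did with the higher pseudocount (adjusted p = 0.0456) and with a trend and robust eBayes (0.0429). Hdac1 was not called (log2 change 0.51, adjusted p = 0.0786), but was with the replicate block (0.0396), with a trend and robust eBayes (0.0499) and without 6 h replicate 2 (0.0431). Gsn (0.37, adjusted p = 0.391) and the monocarboxylate transporter Slc16a1 (0.29, adjusted p = 0.249) were not called.

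In all, 665 genes were higher and 490 lower at 6 h than at 0 h, of which 214 and 120 changed by at least 2-fold. The counts were 342 and 160 without 0 h replicate 1, 299 and 183 without 0 h replicate 2, 360 and 286 without 6 h replicate 1, and 403 and 255 without 6 h replicate 2. With no filter on low values they were 272 and 158.

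Of the 28 gene lists, 3 were higher and 2 were lower at 6 h by camera with the preset correlation, and none of the 5 calls held with an estimated correlation. Among 27 tested genes of glycolysis and hypoxia, 7 rose (8 adjusted over the list alone; adjusted p = 0.0311, and 0.451 with an estimated correlation). The glucose transporter Slc2a1 rose 2.30-fold, the phosphofructokinase Pfkp 2.07-fold, Bnip3 2.01-fold and Ndrg1 1.94-fold, the last not called without 0 h replicate 2 (adjusted p = 0.0701). Of 46 lysosome and autophagy genes, 5 rose (5 adjusted over the list alone; adjusted p = 0.0311, and 0.2 with an estimated correlation), among them Atg12, Ulk1, the sialidase Neu1 and Npc1, with log2 changes of 1.24, 0.97, 0.85 and 0.70. Of 18 neuronal genes, 7 rose (9, and 1 lower, adjusted over the list alone; adjusted p = 0.0152, and 0.2 with an estimated correlation). The vesicle GTPase Rab3a rose from 39.5 ± 18.4 to 262.2 ± 36.4, the kinesin Kif5c from 9.3 ± 9.62 to 84.75 ± 24.5, Stx1a from 287.8 ± 16.5 to 520 ± 33.2 and Eno2 from 48.9 ± 20.6 to 100.8 ± 6.58.

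The lists of mitotic and of ribosome biogenesis genes were called lower at 6 h, but most of their genes were not. Of 43 genes of mitosis and G2/M, 6 fell (8 adjusted over the list alone; adjusted p = 0.00115, and 0.2 with an estimated correlation). Ccna2, Plk1, Kif23 and Ect2 fell by 0.81, 0.81, 0.78 and 0.77 on the log2 scale. Of 47 genes of ribosome biogenesis and MYC targets, 5 fell (4 adjusted over the list alone; adjusted p = 0.0311, and 0.264 with an estimated correlation), with Gnl3 at -1.16, Utp20 at -0.90, Nop56 at -0.81 and Grwd1 at -0.74.

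Several calls at 6 h were lost when 1 array was left out. Some were lost without any of several arrays, so the loss does not point to 1 array. Npc1 lost its call without each of the 0 h and 6 h arrays, with log2 changes of 0.58 to 0.826. The glycolysis list was not called without 6 h replicate 2 (adjusted p = 0.0653), the lysosome list without 0 h replicate 2 (0.0706) or 6 h replicate 1 (0.082), and the ribosome list without 0 h replicate 2 (0.105) or 6 h replicate 2 (0.0693). Ccna2, Plk1, Kif23, Ect2, Nop56, Grwd1, Atg12, Ulk1, Npc1, Stx1a and Eno2 each lost the call without at least 1 of the 0 h or 6 h arrays, with adjusted p-values of 0.051 to 0.272. With no filter the adjusted p of 10 of the genes named, Plk1, Kif23, Ect2, Ndrg1, Stx1a, Eno2, Nop56, Grwd1, Atg12 and Npc1, was 0.0504 to 0.138. Eno2 also lost its call with the higher pseudocount (0.106), all named probe sets (0.053), a trend and robust eBayes (0.0909) and only the 4 arrays compared (0.0513). Under the stricter filter, the glycolysis (adjusted p = 0.191), lysosome (0.0621) and neuronal (0.227) lists were not called, and the neuronal list was not called without a filter (0.245).

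After 12 h, Fos remained the most increased gene, at 2101 ± 457 (log2 change 4.60 ± 0.22, adjusted p = 3.6e-06). Mmp10 (1420450_at), the secreted metalloproteinase stromelysin-2, rose from 18.75 ± 1.63 to 831.7 ± 182, a log2 change of 4.07 ± 0.32 (2.70 to 4.96 over the alternatives). Ddit3 (1417516_at), a transcription factor of the integrated stress response, rose from 378.3 ± 96.6 to 3554 ± 546, or 8.81-fold. Ccnd1 (1448698_at) fell to 1465 ± 84, a log2 change of -2.92 ± 0.16 (adjusted p = 3.6e-06), and Hmga2 (1422851_at) fell from 7086 ± 170 to 843.2 ± 206, a log2 change of -3.04 ± 0.21.

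Txnip, Egr1 and Ccn1 were again among the largest rises at 12 h (13.6-fold, 8.12-fold and 7.85-fold), joined by the brain-type creatine kinase Ckb and the receptor-modifying protein Ramp3 (6.98-fold and 6.96-fold). The actin-binding protein Cotl1 rose from 32.55 ± 18.6 to 418 ± 60.7 and Prtn3 from 10.9 ± 2.69 to 263 ± 37.2, with log2 changes that ranged from 1.77 to 3.47 and from 1.49 to 3.84 over the alternatives. The largest fall was that of Fst (9.66-fold), and after Hmga2 and Ccnd1 came Cd14, Tacc2, Cutal, the membrane metalloproteinase Mmp14, the kallikrein Klk10, the phosphatase Ptprb and Klhl1 (4.77-fold to 5.10-fold), Klhl1 with a 12 h signal of 7.85 ± 1.48 and log2 changes of -3.39 to -1.08 over the alternatives. Krt20 rose to 8066 ± 27.9 (log2 change 2.55 ± 0.24, adjusted p = 7.52e-05). Hdac1 rose from 891.7 ± 21.5 to 1789 ± 150 (adjusted p = 0.00223), and Myc was 2.36-fold lower than at 0 h (adjusted p = 0.000942). Cdkn1a (log2 change -0.17, adjusted p = 0.485), Gsn (0.37, adjusted p = 0.293) and Slc16a1 (-0.12, adjusted p = 0.573) were not called.

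At 12 h, 1332 genes were higher and 1281 lower than at 0 h, 464 and 389 of them by at least 2-fold. The counts were 879 and 846 without 0 h replicate 2 and 886 and 846 without 12 h replicate 2, and the lower genes were 779 without 0 h replicate 1.

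The called lists at 12 h were 3 higher and 3 lower, none of them called with an estimated correlation. Of 38 genes of DNA replication and S phase, 23 fell (26, and 1 higher, adjusted over the list alone; adjusted p = 1.01e-07, and 0.081 with an estimated correlation). Thymidine kinase Tk1 fell from 2597 ± 102 to 656 ± 178, and Hells, Dbf4 and the ribonucleotide reductase subunit Rrm2 fell by 1.94, 1.61 and 1.35 on the log2 scale. Of 43 mitotic genes, 24 fell and 1 rose (29 and 1 adjusted over the list alone; adjusted p = 6.51e-09, and 0.0633 with an estimated correlation). Cdc20, Cenpa, Ccna2 and Aurka fell by 1.65, 1.56, 1.45 and 1.42 on the log2 scale, while Pttg1, which encodes the separase inhibitor securin, was the member that rose, with a log2 change of 0.85. Of 47 ribosome biogenesis genes, 25 fell (31 adjusted over the list alone; adjusted p = 5.56e-08, and 0.0607 with an estimated correlation), led by Utp20 (4.10-fold), Gnl3 (3.26-fold), Gar1 (2.95-fold) and Grwd1 (2.85-fold).

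Glycolysis and hypoxia genes were higher at 12 h, with 13 rises and 2 falls among 27 (13 and 2 adjusted over the list alone; adjusted p = 0.0104, and 0.378 with an estimated correlation). Pfkp, Ndrg1, Bnip3 and the prolyl hydroxylase Egln3 rose by log2 changes of 2.32, 2.10, 1.83 and 1.60 (0.77 to 2.35 for Egln3 over the alternatives), while the 2 that fell were the hexokinase Hk2 and the phosphofructokinase Pfkl. Of 46 lysosome and autophagy genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone; adjusted p = 0.00115, and 0.0867 with an estimated correlation). Atg12, Gabarapl2, the acid lipase Lipa and the proton pump subunit Atp6v0d1 rose by log2 changes of 1.52, 1.10, 0.96 and 0.88, Lipa not being called without 0 h replicate 2 (adjusted p = 0.0644). Of 18 neuronal genes, 13 rose and 1, L1cam, fell (13 and 1 adjusted over the list alone; adjusted p = 0.00016, and 0.0867 with an estimated correlation). Rab3a and Kif5c were at 266.2 ± 23 and 133 ± 19.6 (log2 changes of 1.24 to 2.58 and 0.93 to 3.14 over the alternatives), Bex2 rose from 32.8 ± 18.8 to 158.8 ± 7.14, and the adhesion molecule Ncam1 rose from 191.2 ± 6.58 to 602.8 ± 30.1. Under the stricter filter the glycolysis list (adjusted p = 0.0621) and the neuronal list (0.116) were not called. The interferon and antigen presentation list (7 higher and 3 lower, adjusted p = 0.0802) and the fatty acid oxidation list (11 higher and 3 lower, adjusted p = 0.0906) were not called at 12 h. Without 12 h replicate 1 their median log2 changes were 0.487 and 0.346. Both were called with all named probe sets (0.000931 and 0.00382), where several probe sets of 1 gene count as separate members. The interferon list was also called without 0 h replicate 2 (0.0491), with no filter (0.0203) and under the stricter filter (0.0131), of a range of 0.000931 to 0.378 over the alternatives (0.00382 to 0.451 for fatty acid oxidation).

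After 24 h, the largest rise was that of Mmp10, to 2715 ± 452, a log2 change of 5.75 ± 0.32 (4.27 to 6.66 over the alternatives, adjusted p = 1.67e-06). Fos (1738 ± 238) and Egr1 (6927 ± 101) were still far above their 0 h signals, 20.3-fold and 11.4-fold. Krt20 (1426284_at) reached 15290 ± 4050, a log2 change of 3.44 ± 0.24 (adjusted p = 5.03e-06). Hmgb2 (1452534_a_at), a chromatin protein of the high mobility group, fell from 1946 ± 23.6 to 78.7 ± 25.2, a log2 change of -4.18 ± 0.18 (adjusted p = 9.65e-07). Ccnd1 fell to 815.9 ± 43.3, 13.3-fold below 0 h, and Hmga2 to 494.2 ± 16.6, 13.5-fold below.

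**Figure D1:**
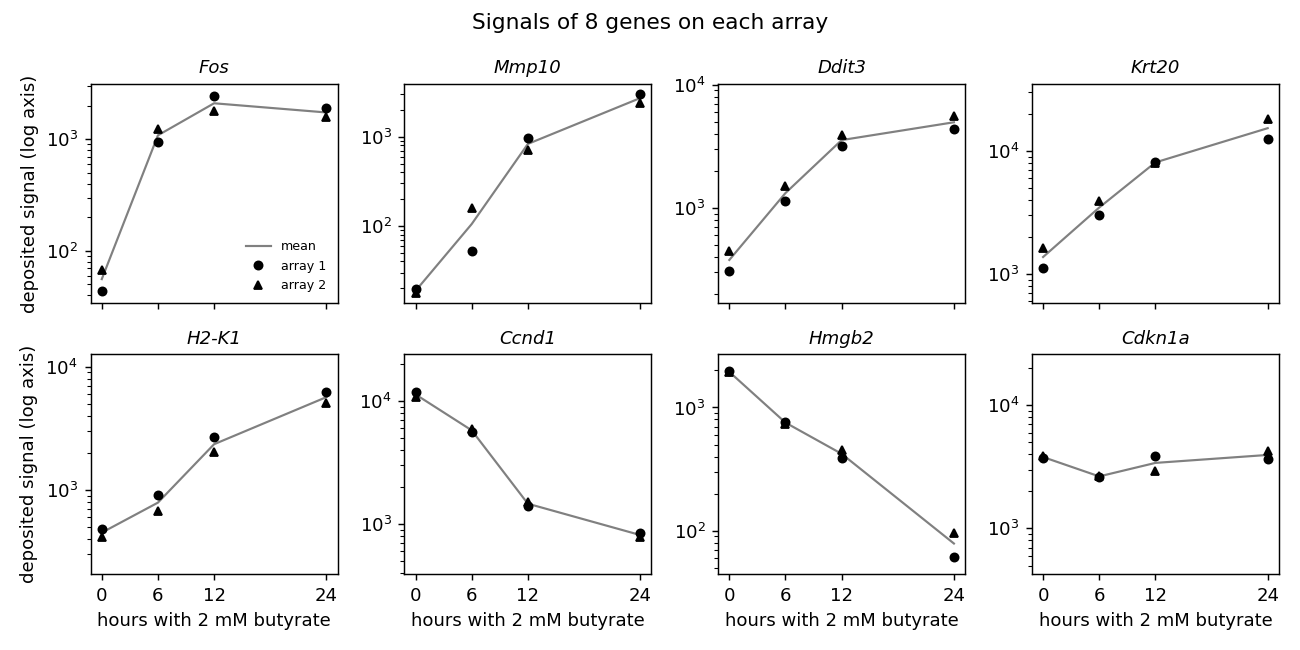
Deposited signal (log axis) of 8 genes against hours with 2 mM butyrate; points are single arrays, 2 per time, and lines join the means. Fos, Mmp10, Ddit3, Krt20 and H2-K1 were higher at 24 h than at 0 h, Ccnd1 and Hmgb2 were lower, and Cdkn1a was at 3797 at 0 h and 3949 at 24 h.

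The other leading rises at 24 h were Txnip (17.6-fold), Ddit3 (12.3-fold), the MHC class I gene H2-K1 (11.8-fold) and Ckb (11.3-fold). The zinc finger transcription factor Plagl1 rose from 13.3 ± 6.08 to 527.3 ± 7.5 and Prtn3 from 10.9 ± 2.69 to 419.8 ± 33.4, with log2 changes that ranged from 2.21 to 4.68 and from 1.98 to 4.51 over the alternatives. The other leading falls were Fst (12.9-fold), the S phase and mitotic cyclin Ccna2 (9.95-fold), Tk1 (8.24-fold), the mitotic kinase Pbk (8.15-fold), Pimreg (7.43-fold), the RNA-binding protein Rbmx (7.36-fold) and the mitotic kinesin Kif20a (7.15-fold). Gsn, which encodes the actin-severing protein gelsolin, rose from 5595 ± 1530 to 11720 ± 2860 (log2 change 1.07 ± 0.26, adjusted p = 0.00664), a call lost without 0 h replicate 1 (adjusted p = 0.0684) or 24 h replicate 1 (0.0605). Hdac1 was 2.01-fold higher (adjusted p = 0.00113) and Myc 2.10-fold lower (adjusted p = 0.00123). Cdkn1a, at 3949 ± 385, was not called (log2 change 0.05, 95% interval -0.34 to 0.45, adjusted p = 0.827), and neither was Slc16a1 (log2 change -0.16, adjusted p = 0.435).

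At 24 h, 1806 genes were higher and 1724 lower than at 0 h, together 48.1% of the 7340 tested, with 679 and 700 changed by at least 2-fold. None of the alternatives run moved either count by over 1.5 times, except the fold threshold itself.

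**Figure D2:**
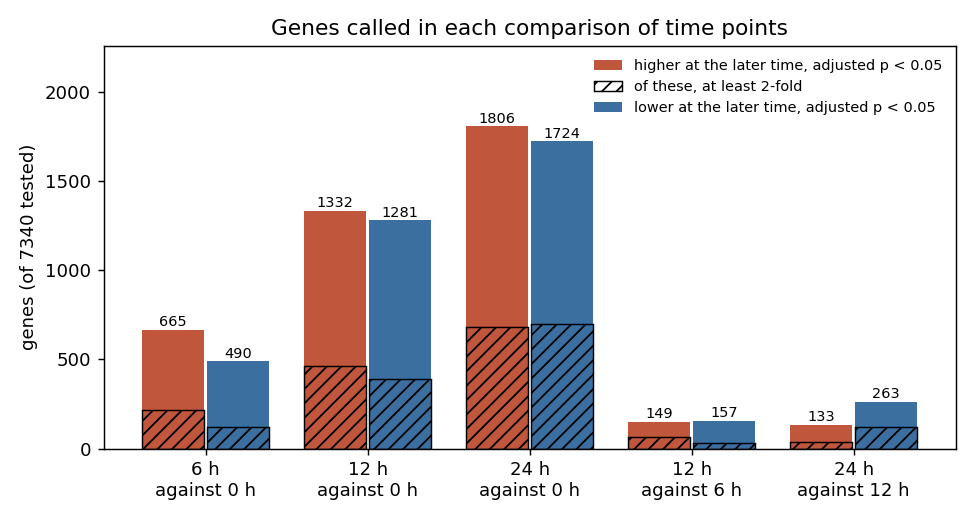
Number of genes (of 7340 tested) higher or lower at the later of the 2 times named, at an adjusted p under 0.05 from limma with 2 arrays per time; hatched parts are genes that changed by at least 2-fold. The comparisons with 0 h grow from 665 and 490 genes at 6 h to 1806 and 1724 at 24 h, and the steps between neighbouring later times hold 133 to 263 genes in each direction.

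At 24 h, 4 lists were lower, and the cell cycle lists were lower almost throughout. Of 43 mitotic genes, 41 fell (42 adjusted over the list alone; adjusted p = 7.12e-21, and 0.0502 with an estimated correlation). Ccna2, Kif20a, Cdc20 and Cenpa led them, with log2 changes of -3.31, -2.84, -2.84 and -2.80, and Pttg1 was again the 1 member that rose (0.97). Of 38 DNA replication genes, 35 fell (35 adjusted over the list alone; adjusted p = 3.1e-16, and 0.0502 with an estimated correlation). Tk1, Rrm2, Hells and the replication licensing factor Cdc6 led (-3.53 to -1.42 over the alternatives for Cdc6, with a 24 h signal of 14.65 ± 0.919), and all of the tested subunits Mcm2 to Mcm7 of the replicative helicase fell, with log2 changes of -1.40 to -2.59. Of 47 ribosome biogenesis genes, 39 fell (40 adjusted over the list alone; adjusted p = 2.74e-11, and 0.0502 with an estimated correlation), with Nop56 4.98-fold, Grwd1 4.73-fold, Utp20 4.12-fold and Gar1 3.66-fold lower.

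The unfolded protein and integrated stress response list was lower at 24 h, with members in both directions. Of its 42 tested genes, 18 fell and 5 rose (18 and 5 adjusted over the list alone; adjusted p = 0.0408, and 0.224 with an estimated correlation). Nupr1 fell from 1621 ± 3.89 to 356.6 ± 5.59, the mitochondrial serine enzyme Shmt2 from 1775 ± 289 to 547 ± 11.1, the transcription factor Xbp1 from 2240 ± 455 to 789 ± 172 and Mthfd2 from 843 ± 8.84 to 381 ± 134. The 5 that rose were Ddit3 (log2 change 3.62), Atf3 (2.23), Cebpb (0.93) and Chac1 (0.59), which are transcription factors and a glutathione-degrading enzyme, and the tryptophan tRNA ligase Wars (0.45). The call was lost without 0 h replicate 1 (adjusted p = 0.0646), without 24 h replicate 2 (0.0859) and under the stricter filter (0.116).

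The 5 lists that were higher at 24 h covered lysosomes, energy metabolism, antigen presentation and neuronal genes. Of 46 lysosome and autophagy genes, 28 rose (28 adjusted over the list alone; adjusted p = 3.93e-06, and 0.0607 with an estimated correlation), with Atg12, Gabarapl2, Atp6v0d1 and Map1lc3a 3.61-fold, 3.19-fold, 2.93-fold and 2.50-fold higher. Of 27 glycolysis and hypoxia genes, 17 rose and 5 fell (17 and 5 adjusted over the list alone; adjusted p = 0.00244, and 0.315 with an estimated correlation). Ndrg1 rose from 759.7 ± 219 to 7181 ± 25.2 and Pfkp from 60 ± 9.9 to 685.4 ± 2.47. Bnip3 was 4.05-fold higher and Egln3 rose from 21.9 ± 20.4 to 178 ± 6.72 (log2 changes of 1.04 to 2.83 over the alternatives), and Hk2, Pfkl, Ldha, Egln1 and Higd1a fell. Of 29 fatty acid oxidation and ketogenesis genes, 15 rose and 4 fell (16 and 4 adjusted over the list alone; adjusted p = 0.0408, and 0.378 with an estimated correlation). Both subunits of the mitochondrial trifunctional protein, Hadhb and Hadha, rose 2.40-fold and 2.18-fold, the transport protein Slc27a1 2.37-fold and the carnitine palmitoyltransferase Cpt1a 2.19-fold, while Plin2, Eci1, Fabp5 and Acsl5 fell. The fatty acid oxidation call ended without 0 h replicate 1 (adjusted p = 0.0534), 0 h replicate 2 (0.0501) or 24 h replicate 2 (0.103), under the stricter filter (0.116) and with no filter (0.0658).

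Among 17 genes of the interferon response and antigen presentation, 11 rose and 3 fell at 24 h (12 and 3 adjusted over the list alone; adjusted p = 0.0272, and 0.299 with an estimated correlation). H2-K1 rose from 450.4 ± 49.4 to 5669 ± 858, the MHC class I light chain B2m from 119.8 ± 0.212 to 1232 ± 290, H2-D1 from 1092 ± 366 to 6735 ± 1590 and the class II invariant chain Cd74 from 84.15 ± 32.6 to 302.4 ± 100. The 3 that fell were the interferon-induced genes Ifit2 and Ifit3 and the immunoproteasome subunit Psmb10, with log2 changes of -1.72, -1.43 and -1.02. The probe sets of H2-K1 and H2-D1 (1425336_x_at and 1425545_x_at) can also bind transcripts of related class I genes, so which class I gene they report is uncertain. Other named genes with x_at probe sets were Ccn1, Cotl1, Plagl1, Lce1h, Stx1a, Rrm2, Shmt2 and Gsn. Those with s_at probe sets were Tlr3, Sco2, Pbk, Ndrg1, Nop56, Gar1, Lipa and Xbp1. Their signals may likewise include other transcripts. Of 18 neuronal genes, 15 rose (15, and 1 lower, adjusted over the list alone; adjusted p = 3.93e-06, and 0.0633 with an estimated correlation). Under the stricter filter, which left 5 members, the neuronal list was not called (0.0875). Its median log2 changes at 6, 12 and 24 h were 0.56, 0.94 and 1.4, but 0.10, 0.24 and 0.64 with no filter (53 members) 0.559, 0.705 and 0.877 under the stricter filter, and 0.29, 0.57 and 0.85 with the higher pseudocount. Rab3a, Kif5c, Ncam1 and Bex2 rose to 24 h signals of 407 ± 27.1, 201.8 ± 21.8, 1173 ± 65.8 and 237.8 ± 57.8. Ncam1 was 5.39-fold higher, and the log2 changes of the other 3, with low 0 h signals, ranged from 1.68 to 3.18, from 1.26 to 3.72 and from 1.18 to 2.65 over the alternatives.

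**Figure D3:**
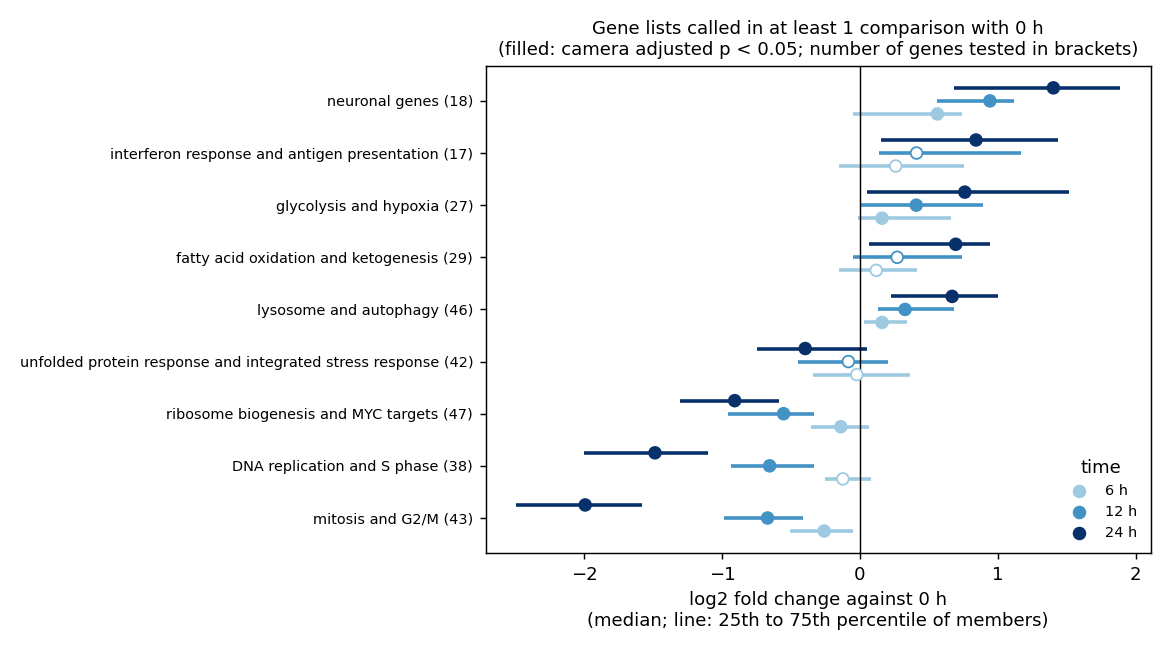
Median log2 fold change against 0 h of the 9 gene lists called in at least 1 comparison, with lines from the 25th to the 75th percentile of the members; filled points mark a camera adjusted p under 0.05. The mitosis list had a median of -0.26 at 6 h and -1.99 at 24 h, and the DNA replication list -0.12 and -1.49.

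The other 19 lists were not called at 24 h. Of the CDK inhibitors and p53 targets, 9 of 27 rose and 4 fell (10 and 4 adjusted over the list alone; adjusted p = 0.657): the CDK inhibitor genes Cdkn1c, Cdkn2a and Cdkn2d rose by log2 changes of 2.09, 0.90 and 0.80, and Zmat3, Phlda3, Ei24 and Aen fell. Of 24 histone deacetylase and acetyltransferase genes, 4 rose and 9 fell (4 and 9 adjusted over the list alone; adjusted p = 0.64), with Hdac5 at 1.3, Hdac7 at -1.86, Hdac2 at -0.43 and the acetyltransferase Kat2b at -1.22. Of 8 histone genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.829); the linker histones H1f2 and H1f10 rose by 1.72 and 1.80 on the log2 scale and Macroh2a2 fell by 2.20 on the same scale. Of 12 genes of absorptive colonocyte differentiation, Krt20 rose and Cdx2 and Emp1 fell (1 and 2 adjusted over the list alone; adjusted p = 0.885). Among the 11 Wnt targets and progenitor genes, 3 rose and 4 fell (3 and 5 adjusted over the list alone; adjusted p = 0.657); Myc, Ccnd1, Bmi1 and Cdca7 fell, and Cd44, Ephb3 and Apcdd1 rose.

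Of 25 pro-apoptotic genes, 8 rose and 4 fell at 24 h (8 and 4 adjusted over the list alone; adjusted p = 0.64), with the BH3-only gene Bcl2l11 at 1.97 and Bok at -2.26 on the log2 scale. Of 14 anti-apoptotic genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.687), with Bcl2l1 at -1.09. Of 38 epithelial junction and keratin genes, 11 rose and 10 fell (11 and 10 adjusted over the list alone; adjusted p = 0.973), with the plakophilin Pkp1 at 2.06 and the transcription factor Ehf at -1.73. Of 37 actin cytoskeleton and smooth muscle genes, 12 rose and 10 fell (12 and 10 adjusted over the list alone; adjusted p = 0.867), with Cnn1 at 2.16 and Tpm1 at -2.42. Of 18 mesenchymal and matrix genes, 6 rose and 4 fell (6 and 4 adjusted over the list alone; adjusted p = 0.64), with the intermediate filament gene Vim at 3.14 and Mmp14 at -1.92. Among 7 skeletal and cardiac muscle genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone; adjusted p = 0.643).

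Of 39 genes of oxidative stress, glutathione and metallothionein, 14 rose and 11 fell (14 and 11 adjusted over the list alone; adjusted p = 0.64), with the metallothioneins Mt1 and Mt2 at 1.90 and 1.58 and the glutathione enzymes Gclm and Gsr at -1.70 and -1.42. Of 21 heat shock genes, 3 rose and 6 fell (3 and 6 adjusted over the list alone; adjusted p = 0.405), with Hspb1 at 2.25. Of 16 NF-kB targets, cytokines and chemokines, 6 rose and 6 fell (6 and 7 adjusted over the list alone; adjusted p = 0.977), with the chemokine Ccl20 at 2.23 and Il33 at -1.29. Of 35 immediate early and growth factor genes, 9 rose and 7 fell (9 and 7 adjusted over the list alone; adjusted p = 0.561): beside Fos and Egr1, Junb rose by 1.68, while Fosl1 and the kinase Sphk1 were at -0.94 and -1.78. Of 25 TGF-beta and BMP response genes, 4 rose and 9 fell (4 and 9 adjusted over the list alone; adjusted p = 0.492), with Bmp4 at 2.18 and the receptor Tgfbr2 at -1.45. Of 24 cholesterol synthesis genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone; adjusted p = 0.153). Of 56 oxidative phosphorylation genes, 11 rose and 3 fell (9 and 2 adjusted over the list alone; adjusted p = 0.269). Of 11 reference genes, 3 fell (3 adjusted over the list alone; adjusted p = 0.643): Hprt, Ywhaz and Tfrc. The median, the mean and the test of a list differed in sign for 10 lists at 6 h, 4 at 12 h and 3 at 24 h, none of them called.

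Between 6 h and 12 h, Mmp10 rose from 105.2 ± 74.4 to 831.7 ± 182 (log2 change 2.75 ± 0.32, adjusted p = 0.00445). Sh3gl3 rose from 10.8 ± 3.82 to 158.2 ± 12.6, and the semaphorin receptor Plxnd1 and the cornified envelope gene Lce1f rose 3.23-fold and 3.17-fold. Their log2 changes ranged over the alternatives from 1.04 to 3.16 for Sh3gl3, from 0.97 to 2.11 for Plxnd1 and from 0.76 to 2.50 for Lce1f, with low 6 h signals. Ccnd1 fell from 5772 ± 277 to 1465 ± 84 (adjusted p = 0.000901), and Klk10, the chloride channel Ano1 and Hells fell by 1.73, 1.51 and 1.38 on the log2 scale. Ano1 lost its call without 12 h replicate 2 (adjusted p = 0.115), 6 h replicate 1 (0.106) or 6 h replicate 2 (0.0851), with a pseudocount of 8 (0.0511) and from the 4 arrays compared alone (0.0725), and Hells without the same arrays (0.0944, 0.0661 and 0.0571). In all, 149 genes rose and 157 fell, against 267 and 314 with the replicate block. With a pseudocount of 8 the falls numbered 95. The counts were 32 and 14 from the 4 arrays compared alone, and 0 and 1 (Ccnd1) with no filter, where 909 and 767 genes had an unadjusted p under 0.05 in limma. Without 6 h replicate 1, 6 h replicate 2, 12 h replicate 1 or 12 h replicate 2 the rises numbered 56, 45, 27 and 24 and the falls 17, 15, 15 and 13. Without 0 h replicate 1 or 0 h replicate 2 the falls numbered 84 in each case.

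Between 12 h and 24 h, the cornified envelope gene Lce1h rose from 100.8 ± 79.7 to 640.8 ± 105, Lce1f from 111.2 ± 23 to 541.4 ± 34.4 and the keratin-associated gene Krtap1-5 from 50.35 ± 5.73 to 265 ± 58.2. The glutathione transferase Gstk1 rose from 32.5 ± 40.6 to 203.6 ± 3.46 (log2 changes of 1.07 to 2.89 over the alternatives). The mitotic checkpoint kinase Bub1 fell from 1079 ± 12.3 to 243.1 ± 18.5, Pbk from 848.4 ± 45.6 to 191.4 ± 23.1 and Shcbp1 from 969.8 ± 74.7 to 224.8 ± 12.1, as did Hmgb2 (log2 change -2.05 ± 0.18, adjusted p = 0.000437). Lce1h lost its call without 12 h replicate 2 (adjusted p = 0.0764), 24 h replicate 1 (0.0739) or 24 h replicate 2 (0.0524), and Gstk1 without 24 h replicate 1 (0.0579) or 24 h replicate 2 (0.058), and with no filter both lost it (0.0808 and 0.0709). In all, 133 genes rose and 263 fell; the rises were 249 with the replicate block, and both counts were lower with no filter, at 29 and 88. Without 12 h replicate 1, 12 h replicate 2, 24 h replicate 1 or 24 h replicate 2 the rises numbered 66, 28, 30 and 26 and the falls 143, 77, 131 and 121.

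Genes called at 6 h were mostly also called at 24 h. Of the genes higher at 6 h, 82.9% were also higher at 24 h (551 genes), and of those lower at 6 h, 82.7% were also lower at 24 h (405 genes), against means of 397.9 and 303.3 genes for simulated unchanged groups described below, while 8 genes were called in opposite directions at the 2 times. At all 3 later times 539 genes were higher than at 0 h, among them Fos, Egr1, Txnip, Ccn1, Ddit3, Ckb and Krt20, and 384 were lower, among them Fst, Hmga2, Ccnd1, Myc and Nupr1. These comparisons share the 0 h arrays. Independent lists of the same sizes would share 29.7 higher and 20.1 lower genes. In 100 simulations of unchanged groups against the same controls, lists of the same sizes, taken from the top of each ranking, shared a mean of 239.3 and 187.7. Part of the excess over independent lists may come from the shared controls. The simulated lists hold no changed genes, and the shared 0 h arrays gave their log2 changes at 6 h and 24 h a correlation of 0.501. Their overlap therefore does not measure how much of the observed overlap the controls made. The log2 changes at 6 h and 24 h had a covariance of 0.271 over genes, against 0.0201 in the simulation. The spread of the shared 0 h arrays, as estimated between arrays of a time, thus accounts for a small part of that covariance. The counts at all 3 times were 237 and 133 with no filter, 295 and about 1.3e+02 without 0 h replicate 1, 261 and 157 without 0 h replicate 2, 322 and 224 without 6 h replicate 1, and 342 and 205 without 6 h replicate 2. Over all 7340 genes, the standard deviation of the log2 changes was 0.473 at 6 h, 0.66 at 12 h and 0.828 at 24 h.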

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

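The tests of a saturated signal by a count of genes, of probe sets near the background and of RNA from another cell type were set down before their results were seen; those of brighter arrays, RNA quality, hybridisation, array scaling, the second Cdkn1a probe set and the filter were chosen afterwards, although the alternative settings that 2 of them use, and the other settings given here, were fixed earlier.

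The control probe set for the B1 repeat, a short interspersed element of the mouse genome, lies outside the genes compared, and its signal was above both 0 h arrays on all 6 later arrays, the lowest later signal being 1.98 times the highest 0 h signal. Its 0 h signals were 2451 and 3202.9 and its 24 h signals 6347.1 and 10692.7 (log2 change 1.54 ± 0.27, adjusted p = 0.00103 in limma, higher on 2 of 2 arrays). The tables argue against brighter arrays or scaling. The 7 control probe sets for the B2 repeat, Gapdh and Actb had a median log2 change of -0.014 (-0.056 to 0.15). Their mean 0 h signals, 16800 to 26340, leave little room for a rise. A further 7, for B2, 18S and the transferrin receptor, at 0 h signals of 47.3 to 814.2, had -0.457 to 0.273 (4 for pyruvate carboxylase, given further on, had 1.41 to 1.97). A bacterial control probe set, for the 3' part of lys, was called higher at 24 h, from a low 37.15 to 85.55 (log2 change 0.769, adjusted p = 0.00377 in limma). The 5' and middle parts of lys had -0.225 and 0.191 and were not called. A technical rise of a single control probe set is therefore not excluded. RNA quality stays open. No 3' to 5' ratio of Gapdh or Actb at 24 h was more than 0.167 from its 0 h mean on the log2 scale. Both signals of each ratio come from the same bright control probe sets, so a shift could be hidden. The hybridisation difference of the replicate 2 arrays could not make the pattern, since each time has 1 array of each number. Within a replicate number the smallest ratio to 0 h was 2.45. As a hypothesis found and tested on the same arrays, transcripts that carry B1 sequence may be more abundant after butyrate. Time in culture stays open as well, and no other biological explanation was tested.

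Cdkn1a, the gene of the CDK inhibitor p21, was called at no time with the settings of the report, though lower at 6 h with the higher pseudocount (adjusted p = 0.0456) and with a trend and robust eBayes (0.0429, of a range of 0.0429 to 0.25), while 41 of 43 mitotic and 35 of 38 DNA replication genes fell by 24 h (adjusted p = 0.0502 for both lists with an estimated correlation). The tables argue against a saturated signal or the choice of probe set as hiding a 2-fold rise, since a second Cdkn1a probe set, at 438.8 at 0 h and 568 at 24 h, had a log2 change of 0.35 ± 0.17. For saturation this rests on a comparison made after the values were seen, because the number set beforehand, at least 10 genes with a higher 0 h signal that rose 2-fold or more by 24 h, was not reached, with 5 found (Ccn2, Ier3, Akap12, Sqstm1 and Gsn). Of all genes compared, 450 had a higher 0 h signal, up to 27440. A second count, tried later, found 8 genes that began lower and passed 2 times the 0 h signal of Cdkn1a, Krt20 reaching 15290. That number is under 10 as well, so neither count settles the question of saturation. The scaling stays open, because the 2 other scalings, under which the highest log2 change was 0.09, moved the array medians by at most 0.04; so does a rise of less than 2-fold, a rise before 6 h could have been missed, since no array covers it, and its 24 h value ranged from -0.05 to 0.15 over the alternatives, with adjusted p-values of 0.621 to 0.947.

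The neuronal gene list was higher at all 3 later times in cells of an epithelial line, with adjusted p = 0.2, 0.0867 and 0.0633 with an estimated correlation at 6, 12 and 24 h. With no filter (53 members, not 18) the median at 24 h was 0.64 (adjusted p = 8.28e-06, of a range of 1.17e-07 to 0.0875 over the alternatives), which argues against the filter as the whole cause there, but at 6 h it was 0.10 and the call was lost (0.245, of a range of 0.00315 to 0.245), so the 6 h call rests on the filter; under the stricter filter the medians were 0.559, 0.705 and 0.877 with 5 members, and none of the 3 calls was kept. RNA from another cell type stays open: of 9 abundant neuronal transcripts on the array, 1, Syp, was both called higher and above the median signal of 144.7 at 24 h, at 148, fewer than the 3 set beforehand, but Snap25, Stmn2 and Nefl were also called higher, at 76.2, 52.6 and 75.6, and signals so near the background exclude nothing. Signals near the background cannot be told apart from a moderate rise. The 15 members called higher had a median 24 h signal of 247, between the median of all values and the bound of 2 times it. No biological explanation was tested, and butyrate cannot be told apart from time in culture.

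A control probe set for pyruvate carboxylase messenger RNA was also above both 0 h arrays on all 6 later arrays, the lowest later signal being 1.58 times the highest 0 h signal, against 1.19, 0.986 and 0.361 for 3 further probe sets of the same messenger RNA, so that 2 of the 4 did not clear the 0 h arrays; its mean signal went from 20.05 at 0 h to 167.7 at 24 h (log2 change 1.97 ± 0.26, adjusted p = 0.000212). The gene itself, Pcx, was at 91.25, 189.4, 368.2 and 594.8 at 0, 6, 12 and 24 h, with a log2 change of 2.35 ± 0.18 at 24 h (adjusted p = 8.57e-06).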

How the results depend on the processing

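No alternative in this part was chosen after its result was seen. Of 169 results for named genes, 160 were called; 19 of these lost the call under some setting, 19 without some array and 17 were under 2-fold, while 2 uncalled ones gained a call under a setting and 1 without an array. Of 84 list results, 20 were called; beside the estimated correlation, 8 lost the call under a setting and 5 without an array, and 7 and 2 gained one. With all named probe sets the pro-apoptotic list was called at 6 h (adjusted p = 0.00152) and 12 h (0.0143), the NF-kB (0.0345) and TGF-beta (0.0213) lists at 6 h, and the fatty acid oxidation (0.00382) and interferon (0.000931) lists at 12 h. That setting counts several probe sets of 1 gene as separate members of a list. Such probe sets mostly moved together, so these calls may be overstated. The interferon list was called under the stricter filter at 6 h (0.0412) and 12 h (0.0131) and with no filter at 12 h (0.0203). Over the alternatives, the highest adjusted p of these 7 results was 0.378 to 0.75. None of these called results for named genes or lists changed direction under any setting run. Each named gene was followed by 1 probe set, and the direction of other called genes was not followed. The cause of the changes below was not tested, except that no filter tests more genes (12393), 4 arrays give fewer residual degrees of freedom, and a fold threshold removes small changes by construction. Without 1 array, the lone array of that time is assumed to vary like the other groups. For arrays, low signals limit the changes that can be seen, since 21.2% to 26.4% of signals lay below the pseudocount.

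With a pseudocount of 8, genes lower at 12 h than at 6 h numbered 95. With no filter, the counts were 272 higher and 158 lower for 6 h against 0 h, 0 and 1 for 12 h against 6 h (909 and 767 at an unadjusted p under 0.05 in limma), 29 and 88 for 24 h against 12 h, and 237 and 133 for all 3 later times. With only the 4 arrays compared, 12 h against 6 h gave 32 and 14. At 2-fold or more the counts were 214 and 120 at 6 h, 464 and 389 at 12 h, 679 and 700 at 24 h, 64 and 30 for 12 h against 6 h, 38 and 121 for 24 h against 12 h, and 155 and 80 at all 3 times. With the replicate block they were 267 and 314 for 12 h against 6 h and 249 higher for 24 h against 12 h. The block kept 1155 of 1155 calls at 6 h, 2611 of 2613 at 12 h and 3530 of 3530 at 24 h. With further calls added, it called 1595, 3114 and 3969 genes at these times.

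Leaving out 1 array gave ranges of 299 to 610 higher and 160 to 461 lower genes at 6 h, 879 to 1352 and 779 to 1310 at 12 h, 24 to 106 and 13 to 111 for 12 h against 6 h, 26 to 135 and 77 to 271 for 24 h against 12 h, and 261 to 457 and about 1.3e+02 to 332 at all 3 times. The lowest counts at 6 h came without 0 h replicate 2 and 0 h replicate 1, at 12 h without the same arrays, for 12 h against 6 h without 12 h replicate 2, for 24 h against 12 h without 24 h replicate 2 and 12 h replicate 2, and at all 3 times without 0 h replicate 2 and 0 h replicate 1. Both ends are for single arrays, and the ranges of other results are as follows, none of them called in any of these fits. Cdkn1a ranged from -0.381 to 0.038 at 12 h and from -0.045 to 0.152 at 24 h. List medians at 6 h ranged from -0.065 to 0.224 for absorptive colonocyte genes, -0.059 to 0.018 for the unfolded protein response, -0.07 to 0.075 for mesenchymal genes, -0.066 to 0.009 for junctions and keratins, -0.046 to 0.021 for actin genes, -0.107 to 0.155 for skeletal and cardiac muscle genes, -0.087 to 0.091 for oxidative phosphorylation and -0.067 to 0.19 for reference genes. Absorptive colonocyte genes ranged from -0.197 to -0.06 at 12 h and -0.171 to -0.051 at 24 h, where the sign of the test changed, and at 24 h NF-kB targets ranged from -0.13 to 0.012 and junctions and keratins from -0.074 to 0.006.

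The direction of the camera test of uncalled lists changed under other settings as follows, with the median under that setting. Many of these medians kept the sign of the main fit, and some kept its value. With a pseudocount of 8, the unfolded protein response was at -0.022 at 6 h. With the higher pseudocount, NF-kB targets were at -0.087 and junctions and keratins at -0.029 at 24 h. With quantile normalization, oxidative phosphorylation was at 0.041 and reference genes at 0.048 at 6 h, and NF-kB targets at -0.073 at 24 h, where median centring gave -0.056. With no filter, absorptive colonocyte genes were at -0.037, heat shock genes at -0.028, junctions and keratins at 0.009 and skeletal and cardiac muscle genes at -0.025 at 6 h. Under the stricter filter, CDK inhibitors and p53 targets were at -0.019 and actin genes at -0.049 at 6 h, NF-kB targets at 0.324 and actin genes at 0.045 at 12 h, and junctions and keratins at -0.03, actin genes at -0.055 and histone genes at 0.409 at 24 h. With all named probe sets, Wnt targets were at 0.222, the unfolded protein response at -0.042 and mesenchymal genes at 0.04 at 6 h, and heat shock genes at -0.046 and muscle genes at 0.087 at 12 h. With only the 4 arrays compared, the unfolded protein response was at -0.022 at 6 h and NF-kB targets at -0.093 and junctions and keratins at -0.03 at 24 h, and with the replicate block the unfolded protein response was at -0.022 and NF-kB targets at -0.093.

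The called lists had camera adjusted p-values with an estimated correlation of 0.2 for mitosis, neuronal genes and lysosome, 0.451 for glycolysis and 0.264 for ribosome biogenesis at 6 h. At 12 h they were 0.081 for DNA replication, 0.0633 for mitosis, 0.378 for glycolysis, 0.0867 for neuronal genes and lysosome and 0.0607 for ribosome biogenesis. At 24 h they were 0.0502 for DNA replication, mitosis and ribosome biogenesis, 0.224 for the unfolded protein response, 0.378 for fatty acid oxidation, 0.315 for glycolysis, 0.299 for interferon, 0.0633 for neuronal genes and 0.0607 for lysosome. The estimated correlations were -0.028 for neuronal genes, -0.007 for the unfolded protein response, -0.004 for lysosome and 0.008 for ribosome biogenesis. These lie below the preset 0.01, so a larger correlation does not explain why those lists lost their calls. The others were 0.019 for mitosis and interferon, 0.024 for DNA replication, 0.029 for fatty acid oxidation and 0.057 for glycolysis. In the simulation, whose genes were drawn independently, the shifted list also went from a camera adjusted p of 1.17e-16 to 0.0559. A call lost with an estimated correlation therefore need not reflect correlated genes.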

Other observations

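The tests in this part were all chosen after the values were seen. Gene families were formed from the letters before the first digit of a symbol, which gave 77 families with at least 10 tested genes, each tested with camera against 0 h at the 3 later times, with the p adjusted over families and times. At 24 h, 2 families were called: the nucleoporins, which build the nuclear pore, and the intraflagellar transport proteins, which carry cargo along cilia. Of 16 nucleoporin genes (Nup), 11 fell at 24 h, with a median log2 change of -0.81 (adjusted p = 0.00173, and 0.756 with an estimated correlation). Nup85, Nup62, Nup37 and Nup107 had log2 changes of -1.94, -1.64, -1.51 and -1.17. Of 12 intraflagellar transport genes (Ift), 9 rose at 24 h, with a median of 0.81 (adjusted p = 0.0256, and 0.756 with an estimated correlation). At 12 h 6 of them rose, with a median of 0.60 (adjusted p = 0.0283, and 0.756 with an estimated correlation). The Ift family was not called at 6 h, with 2 higher (camera adjusted p = 0.157). Nor was the Nup family called earlier, with 2 lower at 6 h (0.368) and 4 at 12 h (0.187). Ift22, Ift57, Ift81 and Ift140 had log2 changes of 1.5, 1.39, 1.17 and 1.10 at 24 h. Both directions were the same under quantile normalization (medians of -0.77 and 0.82) and median centring (-0.77 and 0.84). These scalings moved the array medians by at most 0.04, so they could not have reversed such changes and are no test of them. In addition, 0 members of either family were in a list fixed in advance.

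Probe sets that name no single gene, because several genes or none are listed, were fitted apart. Of 935 that passed the filter, 194 were higher and 217 lower at 24 h than at 0 h, which is 44% of them, against 48.1% of the named genes.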
